A study of Homo sapiens with 15 samples.

How the data were processed

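Doxycycline-inducible HT115 cells, an established human colorectal cancer line, were profiled by poly(A)-selected RNA sequencing in 5 groups of 3 libraries. The induced protein was GFP (the control), V5-tagged wild-type SOX9 (SOX9_WT) or one of the SOX9 mutants M228, M303 and M379. Induction was with 0.5 µg/ml doxycycline for 24 h. The series text calls M303 a truncated SOX9, while the meaning of M228 and M379 is not given in the sources used here. The series text speaks of 6 experiments in duplicate and the labels give 5 groups in triplicate. The groups used here follow the sample labels. No label says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

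Reads were aligned with STAR 2.7.0a to hg38, per the submitters' processing notes. The authors deposited raw counts per gene, made with featureCounts 2.0.1 and the Ensembl 101 annotation of GRCh38, per the file headers. The recorded command sets no strand option, so reads of both strands were counted together. Reads over exons of overlapping genes on opposite strands thus could not be assigned by strand. Of 54 named genes, 2 share over 20% of their exon bases with a gene on the opposite strand: CA9 with 36.1% and LYZ with 34.7%. Their values are uncertain. The deposited normalized signal values equal those counts divided by 1 size factor per library, as found by dividing one table by the other. There, 3 columns match no sample label and were not used, so no normalized value was used for M379. Trimming and read filters are not given in the sources used here.

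The count table holds 60671 genes, of which 42020 were given a symbol through their Ensembl identifier. Library totals ranged from 3054755 to 31704249 reads. A gene with no read in a library could still be present at up to 0.0896 CPM in the deepest library and 0.912 CPM in the shallowest, the level that 3 reads would give. These limits cover counting error only. No pair of libraries within a group agreed within sampling noise.

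After edgeR's expression filter (filterByExpr) 16160 genes were tested. Libraries were scaled by TMM, and 1 model with a mean per group was fitted to all 15 libraries with edgeR 4.0.16 quasi-likelihood methods in R 4.3.3, which leaves 10 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each of 10 contrasts, and an adjusted p under 0.05 is a call. No option beyond the package defaults was fixed in advance. A fit with robust dispersion was run first, and the defaults were then taken as the main setting; the closing text gives the robust counts. CPM values are TMM-scaled and given as mean ± SD over 3 libraries, and log2 fold changes as estimate ± standard error. Of 40 gene lists fixed before the data were examined, 34 had at least 5 tested members. They were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), again with an estimated correlation, and with fry. The estimated correlation keeps none of the list calls of the 7 contrasts against GFP or SOX9_WT.

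The named genes follow a rule fixed before the data were examined. SOX9 came first. Then came called genes with a symbol, a mean log2 CPM of at least 1 and all 3 libraries of one group on the same side of all 3 of the other. From these the 10 highest and 10 lowest fold changes were taken for each contrast against GFP, 5 and 5 against SOX9_WT, and 3 and 3 between mutants. Up to 4 called members of each list and PROM1, KRT20, LGR5, MKI67 and CDX2 were added. A gene named outside the rule is said to be.

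Whether equal replicate numbers pair the libraries was decided from the correlation of their deviations from the group means alone. The labels do not say that a number marks a day or batch. Every pair correlated above 0.1 for the mutants against GFP, for M303 against SOX9_WT (lowest 0.101) and between mutants. The other contrasts did not meet this for all pairs.

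The steps were tested on simulated data with known answers, on 16160 genes. These data used 1 dispersion per gene for all groups (median 0.0284), while the median within GFP was 0.0975. The recovery and false calls below thus hold for equal dispersion only. For M228 against GFP, 63 of 100 genes changed by 1 log2 unit and 96 of 100 changed by 2 were recovered, with 8 unchanged genes called. For M303 against SOX9_WT, 69 and 99 of 100 were recovered, with 14 unchanged genes called. No gene was called in the wrong direction. Unchanged groups were also simulated 20 times with the dispersion of each group kept, to see how many genes the test calls without an effect. These simulations treat the libraries as independent. A further 20 keep the differences between replicate numbers as estimated by the block, with each group's dispersion around them scaled by 1.25 for the degrees of freedom used, and were tested with and without the block. The estimated differences hold noise, which widens the spread the unblocked test sees. All of these simulations were chosen after the data were seen.

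Alternatives fixed in advance were DESeq2 1.42.0 size factors and its Wald test, no filter and a stricter one (1 CPM in 6 libraries), a replicate block, fits of only the compared groups, limma on log2 of the deposited normalized values with a pseudocount of 1, and leaving out each library. Alternatives chosen after the data were seen were robust dispersion, libraries 2 and 3 of every group, removal of a gene length trend per library, that removal or the estimated correlation with the block, and voom with library quality weights.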

Results

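The series asked what SOX9 and SOX9 mutants do to the transcriptome of HT115 colorectal cancer cells. Expression was measured by RNA sequencing in 15 libraries, 3 for each of GFP, SOX9_WT, M228, M303 and M379. Total counts per library ranged from 3054755 reads (GFP replicate 1) to 31704249 reads (M303 replicate 1). GFP replicate 2 stood apart. It held 4.41% of its reads in ribosomal protein genes, against 2.36% to 3.16% in the other libraries, and the median dispersion within the GFP group was 0.0975, against 0.0104 to 0.0232 in the other groups. Replicate 1 of all groups also differed from replicates 2 and 3, with 2496 genes called by edgeR quasi-likelihood tests.

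SOX9 (ENSG00000125398, GRCh38 chromosome 17, 72121020 to 72126416, plus strand), the transcription factor under study, was measured first in every group. It stood at 119 ± 33.9 CPM in GFP, 213 ± 28.6 CPM in SOX9_WT, 2105 ± 250 CPM in M228, 3009 ± 51.6 CPM in M303 and 2215 ± 158 CPM in M379 (SD, n = 3 each). Against GFP the log2 fold change was 4.14 ± 0.20 in M228, 4.66 ± 0.20 in M303 and 4.21 ± 0.20 in M379, with edgeR adjusted p of 1.77e-08, 4.40e-09 and 1.44e-08. In SOX9_WT the fold change was 0.84 ± 0.18 and was not called (edgeR adjusted p = 0.11). Without GFP replicate 3 it was 1.10 and called. Against SOX9_WT the 3 mutants held 3.30 ± 0.19, 3.82 ± 0.20 and 3.38 ± 0.19 more SOX9 on the log2 scale (edgeR adjusted p = 2.69e-07, 4.47e-08 and 2.04e-07). Any comparison of a mutant with SOX9_WT is thus also one of unequal SOX9 read levels.

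**Figure D1:**
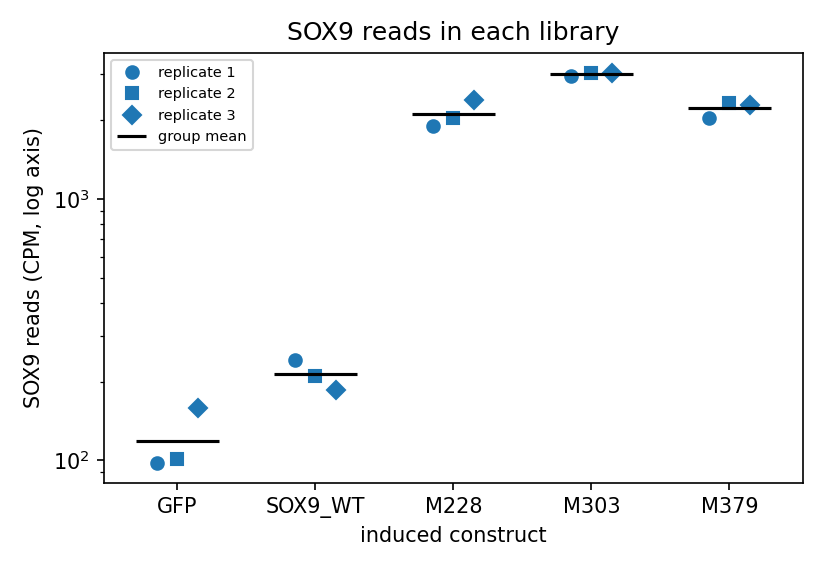
SOX9 reads per library in CPM on a log axis, by induced construct, with a marker for each replicate and a line at the group mean. The mutant groups average 2105, 3009 and 2215 CPM, and SOX9_WT averages 213 CPM against 119 CPM in GFP.

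The comparison of each mutant with SOX9_WT asks what the mutations alter. A fall against SOX9_WT need not be a fall below GFP, and a rise need not be a rise above GFP. APCDD1 held 0.68 to 3.35 CPM in the GFP libraries, 7.60 to 13.9 in SOX9_WT and 1.98 to 3.76 in the mutants. ADRA2A did lie below GFP in M228, at 9.60 to 12.7 against 20.1 to 32.2 CPM. In M228, the genes of the naming rule that rose most, apart from SOX9, were TMEM200A, a transmembrane protein gene, by 3.28 ± 0.42 on the log2 scale, ELFN2 by 3.05 ± 0.26 and NTN4, which encodes a netrin of basement membranes, by 2.54 ± 0.29 (edgeR adjusted p = 0.00183, 3.37e-05 and 0.000636). ADRA2A, an adrenergic receptor gene, fell by 1.92 on the log2 scale from 42.0 ± 5.23 CPM in SOX9_WT (SE 0.17, edgeR adjusted p = 3.37e-05). LYZ, the lysozyme gene of Paneth cells, fell from 2992 ± 500 to 828 ± 189 CPM (n = 3, edgeR adjusted p = 0.0047), with exon overlap on the opposite strand as a limit. MUC17, a membrane mucin gene of enterocytes, changed by -2.24 ± 0.44, APCDD1, a WNT inhibitor gene, by -2.10 ± 0.34 and the urea cycle gene CPS1 by -1.83 ± 0.39. UTS2B rose by 2.05 ± 0.40. In all, 92 genes were called, 46 higher and 46 lower. In 20 simulations of unchanged groups the test called 0 genes here.

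Several gene groups fixed in advance moved in M228 against SOX9_WT by camera's preset correlation. The intestinal stem cell list was lower (18 members, median log2 fold change -0.41), with none of its members called, over all genes or adjusted over the list alone. The camera adjusted p was 1.04e-05, and the adjusted p = 0.24 with an estimated correlation. The WNT target list was lower (20 members, camera adjusted p = 0.00543), with adjusted p = 0.24 with an estimated correlation. APCDD1 and TCF7, a WNT pathway transcription factor gene (-0.64 ± 0.11), fell, and adjusted over the list alone 3 members fell and 1 rose. The chondrocyte list was lower (7 members, camera adjusted p = 0.000534), with adjusted p = 0.24 with an estimated correlation. Its called member was SOX6, a partner of SOX9 in cartilage (-2.06 ± 0.41), and adjusted over the list alone 2 members fell. SOX6 had 186, 66 and 32 reads in SOX9_WT and 21, 7 and 28 in M228. In GFP it had 4, 7 and 21, in libraries of unequal depth. The Notch list was lower too (12 members, camera adjusted p = 0.0116, adjusted p = 0.24 with an estimated correlation), with 4 members lower adjusted over the list alone and none over all genes. The integrated stress response (19 members), heat shock (14), mitosis (19) and enterocyte (23) lists were higher. Their camera adjusted p values were 0.00543, 0.00776, 0.0356 and 0.0356, against an adjusted p of 0.32, 0.80, 0.51 and 0.80 with an estimated correlation. None of their members was called over all genes. Adjusted over the list alone, 4 enterocyte members rose. Of the lists that rose, only the enterocyte list was also called higher in M228 against GFP. Against SOX9_WT, ITGA5, an integrin gene of the mesenchymal list, rose by 1.14 ± 0.23, and CA9 of the hypoxia list fell by 1.16 on the log2 scale, with opposite-strand exon overlap as a limit. ITGA5 had 104, 69 and 179 reads in M228, 65, 68 and 45 in SOX9_WT and 25, 88 and 158 in GFP, in libraries of unequal depth. It was not called in M228 against GFP.

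Leaving out SOX9_WT replicates 1, 2 or 3 gave 31, 27 and 42 called genes, and leaving out M228 replicates 1, 2 or 3 gave 42, 32 and 41. TMEM200A, ELFN2, NTN4, ADRA2A and LYZ stayed called in all 6 of these fits (TMEM200A, with 8, 5 and 14 reads in the SOX9_WT libraries, at up to 4.01), UTS2B, MUC17, CPS1 and CA9 in 0, SOX6 and ITGA5 in 1, TCF7 in 2 and APCDD1 in 3. The stem cell and chondrocyte list calls were kept in all 6, the WNT target call in 5, the Notch, heat shock, stress response and mitosis calls in 4 and the enterocyte call in 3. With libraries 2 and 3 of every group 21 genes were called, a setting chosen after seeing the data, and limma on the deposited values called 41. DESeq2 called 227, the fit of these 2 groups alone 278, edgeR without a filter on low counts 320, removal of the length trend 150 and voom with quality weights 468. Replicate 1 alone has 1 library per group and gives no test.

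In M303, the truncated SOX9, TMEM200A rose by 2.73 ± 0.41 against SOX9_WT, CD200, an immune regulatory membrane protein gene, by 2.18 ± 0.33, CLGN, a chaperone gene, by 2.13 ± 0.31 and UTS2B by 1.92 ± 0.39. Among genes that pass the naming rule's level and separation conditions, those that fell most were APCDD1 (-1.91 ± 0.32), CXCR4, a chemokine receptor gene (-1.82 ± 0.22), SMPD3 (-1.59 ± 0.29), ADRA2A (-1.55 ± 0.16) and SBSPON (-1.45 ± 0.15). The edgeR adjusted p was 0.0106 for TMEM200A, 0.00121 for CXCR4 and 0.000473 for ADRA2A and SBSPON. The serine synthesis gene PHGDH rose by 1.38 ± 0.24 and ETV5, a target of MAPK signalling, by 1.28 ± 0.22, while LYZ fell by 1.44 and CEACAM5, an adhesion gene of colonocytes, by 0.66 on the log2 scale. In all, 62 genes were called, 34 higher and 28 lower. The simulations of unchanged groups called 0.05 genes on average, at most 1.

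The integrated stress response list rose in M303 against SOX9_WT (19 members, camera adjusted p = 7.33e-05, adjusted p = 0.19 with an estimated correlation). PHGDH was its called member, and adjusted over the list alone 3 members rose. The list was lower in SOX9_WT than in GFP (camera adjusted p = 0.00321, not kept with an estimated correlation). It was not called in any mutant against GFP. PHGDH had 497, 233 and 179 reads in M303, 93, 49 and 48 in SOX9_WT and 25, 152 and 132 in GFP, in libraries of unequal depth. Against SOX9_WT the WNT target list fell (camera adjusted p = 0.00146, adjusted p = 0.12 with an estimated correlation), with APCDD1 and TCF7 (-0.68 ± 0.11) called, and 2 members lower adjusted over the list alone. The BMP and TGF-beta list fell (16 members, camera adjusted p = 0.00152, adjusted p = 0.084 with an estimated correlation). None of its members was called over all genes, and 3 were lower adjusted over the list alone. The stem cell list (18 members) and the goblet cell list (11) were lower too, with none of their members called by either count. Their camera adjusted p values were 0.00146 and 0.0301, against an adjusted p of 0.49 and 0.69 with an estimated correlation. The mitochondrial genome (13 members) and NF-kB target (14) lists were lower and the ribosomal protein list (36) higher, at camera adjusted p values of 0.00656, 0.00622 and 0.00622. With an estimated correlation the adjusted p was 0.79, 0.69 and 0.91. The NF-kB list's median was 0.04 and its mean -0.21, so its median and its test differ in sign, and 4 members were lower adjusted over the list alone.

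Leaving out SOX9_WT replicates 1, 2 or 3 gave 10, 9 and 18 called genes, and leaving out M303 replicates 1, 2 or 3 gave 33, 20 and 14. CXCR4, ADRA2A and SBSPON stayed called in all 6 fits, TMEM200A (up to 3.47), CD200 and CLGN in 4, APCDD1, SMPD3 and PHGDH in 2, LYZ and ETV5 in 1 and UTS2B, TCF7 and CEACAM5 in 0. The stress response, WNT target, BMP and TGF-beta and stem cell list calls were kept in all 6, the NF-kB and ribosomal calls in 4 and the goblet cell and mitochondrial calls in 3. Blocking on replicate, 259 genes were called and the Paneth cell list was lower (camera adjusted p = 0.0183, adjusted p = 0.21 with an estimated correlation), and with libraries 2 and 3 of every group, 7. Limma on the deposited values called 10, the fit of these 2 groups alone 118, DESeq2 170, edgeR without a filter on low counts 273, removal of the length trend 105 and voom 1202.

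In M379 against SOX9_WT 20 genes were called, 10 higher and 10 lower. TMEM200A rose by 2.54 ± 0.42, CLGN by 1.88 ± 0.32, ELFN2 by 1.65 ± 0.26 and HGD, a tyrosine breakdown enzyme gene, by 1.30 ± 0.24. APCDD1 (-1.83 ± 0.33), TPPP3 (-1.70 ± 0.26), the chemokine gene PPBP (-1.47 ± 0.24), CXCR4 (-1.42 ± 0.22) and ADRA2A (-0.98 ± 0.16) fell, with edgeR adjusted p from 0.0272 to 0.0436. The integrated stress response and DNA replication lists were higher (camera adjusted p = 0.00319 and 0.00746, adjusted p = 0.48 and 0.61 with an estimated correlation), with none of their members called over all genes and 1 stress response member higher adjusted over the list alone. Neither list was called in M379 against GFP. Against SOX9_WT the stem cell, BMP and TGF-beta, goblet cell and WNT target lists were lower, at camera adjusted p values of 0.00319, 0.00319, 0.0148 and 0.015. The adjusted p with an estimated correlation was 0.61, 0.11, 0.61 and 0.44. APCDD1 was the called member among them. Adjusted over the list alone 3 BMP and TGF-beta members and 2 WNT target members were lower. The ribosomal protein list was higher (camera adjusted p = 0.015, adjusted p = 0.95 with an estimated correlation), with no member called.

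Apart from SOX9, called in all 6 fits with a library left out, the M379 calls were mostly lost in such fits. Leaving out SOX9_WT replicates 1, 2 or 3 gave 2, 1 and 2 called genes, and leaving out M379 replicates 1, 2 or 3 gave 5, 3 and 1. TMEM200A (up to 3.28), ELFN2, HGD and PPBP stayed called in 1 of these 6 fits and CLGN, APCDD1, TPPP3, CXCR4 and ADRA2A in 0. The stress response and BMP and TGF-beta list calls were kept in all 6, the goblet cell and ribosomal calls in 5 and the DNA replication, WNT target and stem cell calls in 4. With libraries 2 and 3 of every group 1 gene was called, but by DESeq2 71, by the fit of these 2 groups alone 165, by edgeR without a filter on low counts 137 and by voom 707. The simulations of unchanged groups called 0.05 genes on average, at most 1.

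The 3 mutants shared 14 calls of the same direction against SOX9_WT, SOX9 left out. CLGN, TMEM200A, CALD1, CHST6, AP1M1 and ELFN2 were higher, and CXCR4, MUC7, NMUR2, PLAT, SBSPON, ADRA2A, TPPP3 and APCDD1 were lower. CALD1, CHST6, AP1M1, MUC7, NMUR2 and PLAT lie outside the naming rule in these contrasts and were chosen after their values were seen. Independent lists of these sizes would share 5.12e-05 higher and 4.93e-05 lower genes. All 3 contrasts use the same SOX9_WT libraries, which cannot be split into parts of at least 2, so part of the overlap may come from them.

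**Figure D2:**
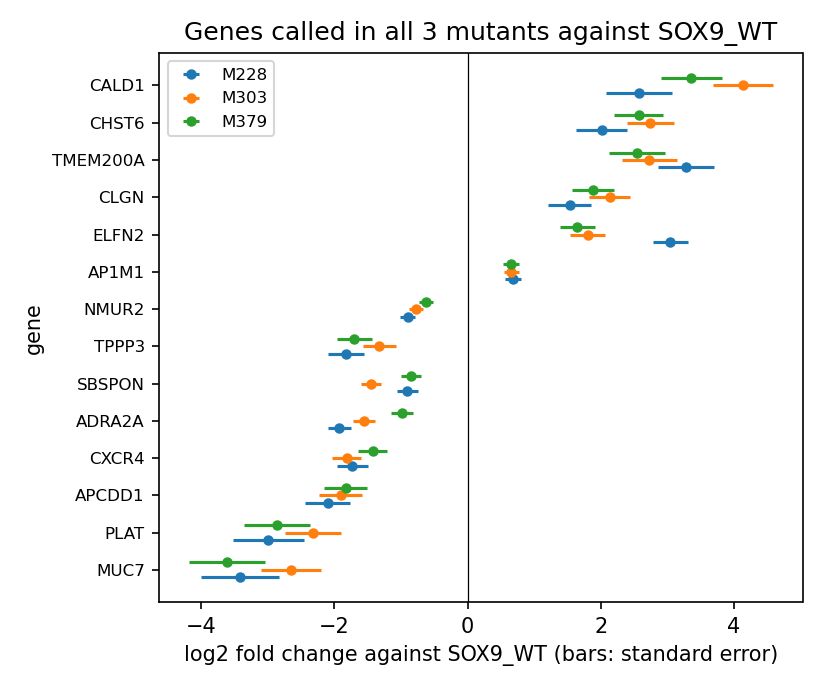
Log2 fold change against SOX9_WT (horizontal axis, bars: standard error) of the 14 genes called in all 3 mutants, with 1 row per gene and a colour per mutant. ADRA2A lies at -1.92 in M228, -1.55 in M303 and -0.98 in M379.

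The 5 markers fixed in advance by name were not called in any contrast by the edgeR fit reported here. KRT20, a keratin of differentiated colonocytes, averaged 1098 ± 207 CPM in SOX9_WT and 640 ± 55.6 CPM in GFP (0.78 ± 0.17, edgeR adjusted p = 0.139). PROM1, a stem-like marker, averaged 86.9 ± 29.9 CPM in SOX9_WT against 44.1 ± 14.9 CPM in M228 (-0.98 ± 0.30, edgeR adjusted p = 0.236). Without a filter on low counts edgeR called both (adjusted p = 0.00212 for KRT20 in SOX9_WT minus GFP and 1.93e-05 for PROM1 in M228 minus SOX9_WT). Blocking on replicate, PROM1 and KRT20 were called lower in M303 than in SOX9_WT by edgeR (-0.85 ± 0.13, adjusted p = 0.00417, and -0.73 ± 0.13, adjusted p = 0.0123, against 0.389 and 0.0905 without the block). M303 was not alone in this: the closing text gives their blocked calls in contrasts whose replicate numbers did not pair by the rule used. Over the 10 contrasts the log2 fold change of LGR5, the crypt stem cell receptor, lay between -0.67 and 0.29, that of MKI67, a proliferation marker, between -0.07 and 0.13, and that of CDX2, an intestinal transcription factor, between -0.28 and 0.27. Single libraries turn these directions: when one was left out, SOX9_WT against GFP ran from -0.060 to 0.70 for LGR5, -0.16 to 0.34 for MKI67 and -0.33 to 0.031 for CDX2.

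The group labelled wild-type SOX9 was compared with GFP, with SOX9 reads of 213 against 119 CPM, a difference that the reported edgeR fit did not call. APCDD1 rose by 2.74 ± 0.38, the protease gene KLK7 by 1.54 ± 0.24, the kinase genes HUNK by 1.26 ± 0.16 and RIPK4 by 0.93 ± 0.15 (edgeR adjusted p = 0.0227, 0.0432, 0.0197 and 0.0432). MIR9-1HG fell by 1.73 on the log2 scale and lies outside the naming rule, chosen after its values were seen. These 5 genes were all that was called. Unchanged groups simulated as independent libraries, with the wide GFP dispersion kept, gave 18.1 calls on average, from 0 to 43, and 18 of 20 simulations gave at least 5. Simulations that also keep the differences between replicate numbers gave at most 1. Whether the count exceeds what is called without an effect thus depends on the simulation, and the fit of these 2 groups alone called 0. DESeq2 called 67, edgeR without a filter on low counts 180, voom 36, removal of the length trend 10 and limma on the deposited values 0, and edgeR had 1723 genes at an unadjusted p under 0.05.

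The WNT target list was higher in SOX9_WT than in GFP (20 members, camera adjusted p = 0.00238, adjusted p = 0.19 with an estimated correlation), with APCDD1 called and 2 members higher adjusted over the list alone. The stem cell, SOX family, extracellular matrix and enterocyte lists were higher, at camera adjusted p values of 0.00248, 0.0115, 0.0047 and 0.00837. With an estimated correlation the adjusted p was 0.48, 0.19, 0.48 and 0.56. No member was called over all genes, and 2, 1, 1 and 3 rose adjusted over the list alone. The ribosomal protein, oxidative phosphorylation, integrated stress response and mitosis lists were lower, at camera adjusted p values of 2.14e-14, 0.000892, 0.00321 and 0.0383. The adjusted p with an estimated correlation was 0.48, 0.60, 0.48 and 0.48. No member was called over all genes, and 1 stress response member was lower adjusted over the list alone. GFP replicate 2, with its high ribosomal share, moves with these lists. Without it the oxidative phosphorylation call was lost (camera adjusted p = 0.648) and the ribosomal median moved from -0.43 to -0.096. The stem cell call was lost without that library as well (camera adjusted p = 0.0559). Leaving out GFP replicates 1, 2 or 3 gave 1, 0 and 38 called genes, and leaving out SOX9_WT replicates 1 or 2 gave 1 each. APCDD1 stayed called in 4 of 6 such fits and KLK7, HUNK and RIPK4 in 2. The WNT target and ribosomal list calls were kept in all 6, the stem cell, matrix, stress response and oxidative phosphorylation calls in 5, the SOX family and enterocyte calls in 4 and the mitosis call in 3. With libraries 2 and 3 of every group 1 gene was called.

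Each mutant was then compared with GFP. In M228, apart from SOX9, LAMA4, a laminin gene, rose by 2.97 ± 0.42, the proteoglycan gene VCAN by 2.73 ± 0.42, ELFN2 by 2.50 ± 0.27, TMEM200A by 2.41 ± 0.41, the monoamine oxidase gene MAOB by 2.27 ± 0.35 and TNFRSF11B, the osteoprotegerin gene, by 2.15 ± 0.34. NTN4 (1.94 ± 0.29), ARSJ (1.78 ± 0.28) and TLR4, a receptor for bacterial lipopolysaccharide (1.57 ± 0.23), rose too. GPX2, a gut glutathione peroxidase gene, fell from 298 ± 162 to 74.9 ± 12.2 CPM (n = 3, edgeR adjusted p = 0.00592), and SHF (-1.79 ± 0.33), RUNX3 (-1.47 ± 0.28), ADRA2A (-1.33 ± 0.17), IGFBP4 (-1.11 ± 0.18) and RILPL2 (-0.85 ± 0.15) fell too. In GFP replicate 1, the shallowest library, LAMA4 and ELFN2 had 7 reads each, VCAN and TMEM200A 6, ARSJ 5 and MAOB 1. The sizes of these rises are thus uncertain. In all, 39 genes were called, 33 higher and 6 lower. Unchanged groups of independent libraries gave 39.3 calls on average (median 31.5), and 8 of 20 gave at least the 38 seen without SOX9. With the replicate differences kept, the simulations gave at most 2, and at most 67 when blocked on replicate, against 180 seen with the block. In the fit of these 2 groups alone 3 genes were called, SOX9, LAMA4 (2.95 ± 0.33) and ELFN2 (2.50 ± 0.24).

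The enterocyte list was higher in M228 than in GFP (23 members, camera adjusted p = 1.94e-06, adjusted p = 0.49 with an estimated correlation). CDHR2, a brush border cadherin gene, rose by 1.27 ± 0.24, and adjusted over the list alone 8 members rose. The extracellular matrix, YAP target, immediate early and MAPK, and epithelial adhesion lists were higher, at camera adjusted p values of 0.000907, 0.0269, 0.0281 and 0.0333. With an estimated correlation the adjusted p was 0.57, 0.86, 0.31 and 0.31. No member was called over all genes and 2 matrix members rose adjusted over the list alone. The ribosomal protein and oxidative phosphorylation lists were lower (camera adjusted p = 4.87e-08 and 0.000351, adjusted p = 0.86 for both with an estimated correlation). Both calls were lost without GFP replicate 2, which carries the high ribosomal share (camera adjusted p = 0.809). The YAP target call was lost without it too. Leaving out GFP replicate 3 gave 143 called genes, and leaving out M228 replicates 1, 2 or 3 gave 23, 15 and 25. LAMA4, VCAN, ELFN2, NTN4, TLR4, GPX2 and ADRA2A stayed called in all 6 such fits, MAOB and ARSJ in 5, IGFBP4 in 4, TMEM200A and TNFRSF11B in 3, SHF in 2 and RUNX3, RILPL2 and CDHR2 in 1. VCAN reached 3.33 and NTN4 2.57 in these fits. The enterocyte and matrix list calls were kept in all 6, the MAPK call in 3 and the YAP and adhesion calls in 2. Blocking on replicate, 181 genes were called and the goblet cell list was lower (camera adjusted p = 0.0248, adjusted p = 0.85 with an estimated correlation), and with libraries 2 and 3 of every group, 9. DESeq2 called 166, edgeR without a filter on low counts 282, removal of the length trend 66 and limma on the deposited values 18.

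In M303 against GFP, COL9A3, a cartilage collagen gene, rose from 2.18 ± 0.797 to 19.8 ± 4.15 CPM (n = 3, 3.09 ± 0.36 on the log2 scale, edgeR adjusted p = 0.00223). In SOX9_WT COL9A3 held 5.64 to 12.7 CPM, above every GFP library, though not called there. LAMA4 (2.27 ± 0.41), the protease inhibitor gene SPINK5 (1.89 ± 0.25), SHROOM4 (1.56 ± 0.23), the desmosomal cadherin gene DSG3 (1.54 ± 0.25), PCBP4 (1.37 ± 0.22), the cathepsin gene CTSV (1.27 ± 0.20), TLR4 (1.26 ± 0.23) and ARHGEF37 (1.01 ± 0.15) also rose. ADRA2A (-0.95 ± 0.16) and RILPL2 (-0.89 ± 0.15) fell. RILPL2, also lower in M228, held 15.97 to 22.8 CPM in GFP, 12.99 to 14.1 in SOX9_WT and 10.1 to 11.4 in M303. It was thus below GFP in SOX9_WT too, though not called there, while ADRA2A was above GFP in SOX9_WT. SI, the sucrase-isomaltase gene of enterocytes, rose by 2.72 ± 0.46. In all, 19 genes were called, 17 higher and 2 lower. Unchanged groups of independent libraries gave 47.5 calls on average, from 10 to 82, and 18 of 20 gave at least the 18 seen without SOX9. With the replicate differences kept, at most 1 was called, and 14 to 88 when blocked on replicate, where 1 of 20 reached the 84 seen with the block. In the fit of these 2 groups alone SOX9 and COL9A3 (3.10 ± 0.31) were called.

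Of the lists in M303 against GFP, the chondrocyte list (7 members) and the immediate early and MAPK list (19) were higher, at a camera adjusted p of 0.00267 for each. The adjusted p with an estimated correlation was 0.56 and 0.11. COL9A3 was the called chondrocyte member, over all genes and adjusted over the list alone, and 2 MAPK members rose adjusted over the list alone. The enterocyte list was higher (camera adjusted p = 0.00267, adjusted p = 0.68 with an estimated correlation), with SI called and 4 members higher and 1 lower adjusted over the list alone. The cholesterol synthesis list was higher (camera adjusted p = 0.0483, adjusted p = 0.83 with an estimated correlation). The goblet cell, NF-kB target, oxidative phosphorylation and ribosomal protein lists were lower, at camera adjusted p values of 0.00267, 0.0023, 0.000443 and 5.72e-07. With an estimated correlation the adjusted p was 0.56, 0.68, 0.77 and 0.77. No member of these 4 was called over all genes, and 2 NF-kB members were lower adjusted over the list alone. Without GFP replicate 2, with its high ribosomal share, the last 2 calls were lost (camera adjusted p = 0.57 and 0.166). The goblet cell, NF-kB target and cholesterol synthesis calls were lost without it too. Leaving out GFP replicate 3 gave 31 called genes, and leaving out M303 replicates 1, 2 or 3 gave 8, 4 and 6. COL9A3 and SPINK5 stayed called in all 6 such fits, ARHGEF37 in 5, SHROOM4 in 4, DSG3 and CTSV in 3, PCBP4 and TLR4 in 2, SI, ADRA2A and RILPL2 in 1 and LAMA4 in 0. The chondrocyte and MAPK list calls were kept in 5, the enterocyte and NF-kB calls in 4 and the goblet cell and cholesterol calls in 3. Blocking on replicate, 85 genes were called, and with libraries 2 and 3 of every group, 4. DESeq2 called 89, edgeR without a filter on low counts 212, voom 42 and limma on the deposited values 4.

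In M379 against GFP, SOX9, COL9A3 (2.83 ± 0.36), SPINK5 (1.90 ± 0.26), SHROOM4 (1.44 ± 0.23), CTSV (1.26 ± 0.20) and ARHGEF37 (0.92 ± 0.15) rose, with edgeR adjusted p from 0.00725 to 0.0487 apart from SOX9, and no gene was lower. COL9A3, ARHGEF37 and SHROOM4 were also above GFP in every SOX9_WT library, though not called there. COL9A3 held 1.52 to 3.07 CPM in GFP, 5.64 to 12.7 in SOX9_WT and 11.6 to 21.7 in M379. ARHGEF37 held 14.3 to 17.03 CPM in GFP, 20.9 to 30.2 in SOX9_WT and 27.2 to 30.7 in M379. SHROOM4 held 2.56 to 3.37, 5.73 to 10.4 and 7.15 to 8.92 CPM in the same groups. Their rise is thus not particular to the mutants by these values. SPINK5 and CTSV lay between GFP and M379 in SOX9_WT. DESeq2 called 50 genes in this contrast, edgeR without a filter on low counts 74, voom 24, and a stricter filter or DESeq2 size factors 3 each, and edgeR had 1094 at an unadjusted p under 0.05. Unchanged groups of independent libraries gave 23.2 calls on average, from 4 to 48, and 19 of 20 gave at least the 5 seen without SOX9. With the replicate differences kept, at most 1 was called, and 7 to 46 when blocked on replicate, where 14 of 20 reached the 16 seen with the block. In the fit of these 2 groups alone SOX9 was the only call. The chondrocyte and extracellular matrix lists were higher, at camera adjusted p values of 0.0415 and 0.00209. The adjusted p with an estimated correlation was 0.52 and 0.40. COL9A3 was called among them, and 2 matrix members rose adjusted over the list alone. The goblet cell, oxidative phosphorylation, NF-kB target and ribosomal protein lists were lower, at camera adjusted p values of 0.00194, 0.00194, 0.0415 and 2.47e-09, with no member called. With an estimated correlation the adjusted p was 0.40, 0.68, 0.67 and 0.65. Without GFP replicate 2, with its high ribosomal share, each of these list calls was lost, and the 1 list called then was another. Leaving out GFP replicate 3 gave 12 called genes, and leaving out M379 replicates 1, 2 or 3 gave 3, 2 and 2. COL9A3 stayed called in all 6 such fits, SPINK5 in 4, CTSV in 2 and SHROOM4 and ARHGEF37 in 0. The matrix list call was kept in 5, the goblet cell call in 4, the chondrocyte call in 3 and the NF-kB call in 2. Blocking on replicate, 17 genes were called, the chondrocyte call was lost (camera adjusted p = 0.136) and the cholesterol synthesis list was higher (camera adjusted p = 0.0182, adjusted p = 0.49 with an estimated correlation), and with libraries 2 and 3 of every group, 3.

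**Figure D3:**
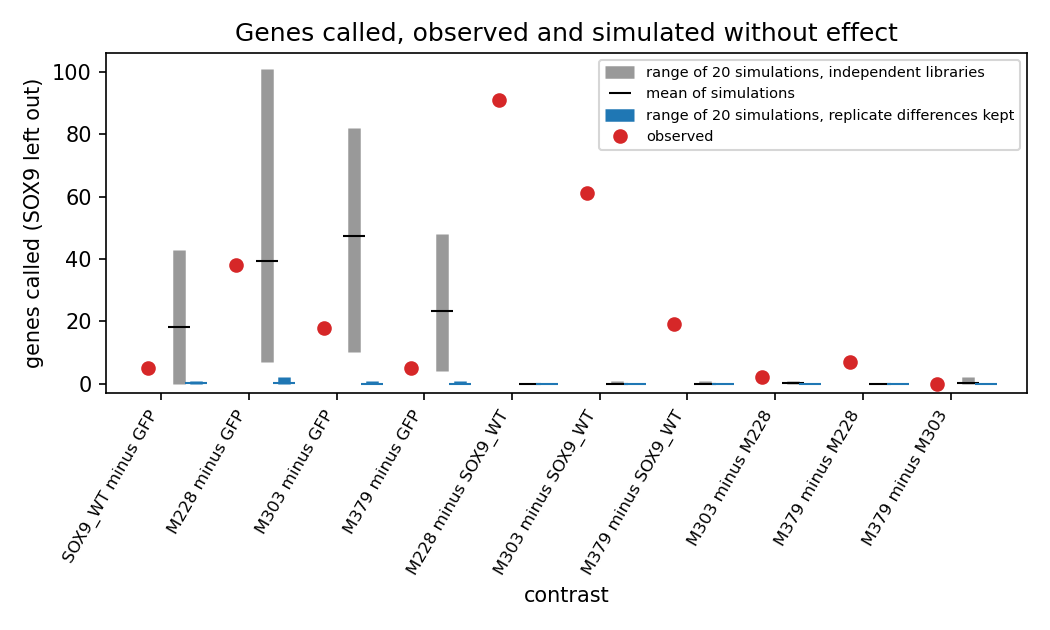
Number of genes called per contrast, SOX9 left out (points), beside the range and mean (ticks) of calls in 20 simulations of unchanged groups with the dispersion of each group, as independent libraries (grey) or with the replicate differences kept (blue). Against GFP the observed 5, 38, 18 and 5 lie within the first ranges and above the second. Against SOX9_WT the observed 91, 61 and 19 lie above both.

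Comparisons between mutants ask whether the mutants differ. COL9A3 was higher in M303 than in M228 by 2.59 ± 0.33 and in M379 than in M228 by 2.33 ± 0.33 (edgeR adjusted p = 0.00702 and 0.0133). NTN4 (-2.04 ± 0.27), ELFN2 (-1.40 ± 0.23) and the kinase inhibitor gene PKIB (-1.23 ± 0.15) were lower in M379 than in M228 (edgeR adjusted p = 0.0101, 0.0433 and 0.00645). In M303 against M228, 2 genes were called (14 blocking on replicate), and in M379 against M228, 7 (25 blocking on replicate). With libraries 2 and 3 of every group 1 gene was called in each. In the first, DESeq2 called 11, edgeR without a filter on low counts 47, removal of the length trend 8, voom 14, a stricter filter 1 and limma on the deposited values 0. In the second, DESeq2 called 23, edgeR without a filter 48 and voom 34. When 1 library was left out, COL9A3 stayed called in 3 of 6 fits in the first contrast and in 1 of 6 in the second, where NTN4 and ELFN2 stayed called in 1 and PKIB in 5. Without M228 replicates 1, 2 or 3, or M303 replicate 1, the M303 contrast had 1 call each. Without M228 replicates 1, 2 or 3 the M379 contrast 4, 2 and 3, and without M379 replicates 1, 2 or 3 the latter had 4, 1 and 0. Between M379 and M303 edgeR called 0 genes, with 137 at an unadjusted p under 0.05. DESeq2 called 0 there, voom with quality weights 1 and edgeR without a filter on low counts 5.

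Fold changes of the 4 SOX9 groups against GFP share the GFP libraries. Their covariance over genes, SOX9 left out, ran from 0.0874 (SOX9_WT and M379) to 0.113 (M228 and M303), and unchanged groups of independent libraries gave 0.112 for each pair. Without GFP replicate 3 alone the observed values were 0.245 to 0.269. Pearson's r ran from 0.593 to 0.813, against 0.754 to 0.792 simulated in this way, across genes that are not independent replicates. The excess covariance lay between -0.0245 and 0.00118, with jackknife standard errors of 0.0836 to 0.105. Simulations that keep the replicate differences gave a covariance of 0.0858 to 0.0872, an excess of 0.000871 to 0.0270. The excess covariance stayed below its standard error in both. That error comes from 3 GFP libraries and is close to the covariance itself, so it could hardly show an excess. Over simulations the SD was 0.00196 to 0.00232 for independent libraries and 0.00182 to 0.00203 with the replicate differences kept. This SD holds the estimated dispersions fixed, so whether an excess exists is left open. The called genes shared by M228 and M303 numbered 6 higher and 2 lower, against 13.4 and 5.45 in the simulations of independent libraries, 0 and 0 in those that keep the replicate differences and 0.0317 and 0.000743 for independent lists. M303 and M379 shared 5 higher and 0 lower, against 10.8 and 3.9 for independent libraries and 0 and 0 with the replicate differences kept. Whether the overlaps exceed those of unchanged groups thus depends on the simulation. The GFP libraries cannot be split into parts of at least 2.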

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

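The tests of ribosomal protein genes, of replicate 1 (except the gene length test) and of the SOX9 reads in SOX9_WT were chosen after the results were seen, while the splits of the libraries were fixed before.

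Among genes named because edgeR called them in a mutant against SOX9_WT, 5 cases were also called in that mutant against GFP and had the opposite sign in SOX9_WT against GFP. The differences below are the contrasts that selected them, not further tests. TMEM200A differed by 3.28 (M228 2.41 ± 0.41, SOX9_WT -0.87 ± 0.51, edgeR adjusted p = 0.00183). ELFN2 differed by 3.05 (M228 2.50 ± 0.27, SOX9_WT -0.55 ± 0.30, edgeR adjusted p = 3.37e-05). NTN4 differed by 2.54 (M228 1.94 ± 0.29, SOX9_WT -0.60 ± 0.31, edgeR adjusted p = 0.000636). ADRA2A differed by -1.92 in M228 (-1.33 ± 0.17) and by -1.55 in M303 (-0.95 ± 0.16), against 0.60 ± 0.16 in SOX9_WT (edgeR adjusted p = 3.37e-05 and 0.000473). The SOX9_WT values against GFP were not called, so their opposite sign is not established.

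Ribosomal protein genes were lower than in GFP in all 4 SOX9 groups, with medians of -0.43 in SOX9_WT, -0.31 in M228, -0.26 in M303 and -0.29 in M379. Without GFP replicate 2 the lowest median among the mutants was 0.033, so in the mutants that 1 library may account for the shift. In SOX9_WT the median without it was -0.096, at the bound of -0.1 set for this test within its spread of 0.079. The camera call was also kept there (adjusted p = 0.00105), so that library and an effect of wild-type SOX9 cannot be told apart; a margin of 1 spread was added to the test after this value was seen. With a gene length trend removed the medians were -0.38 in SOX9_WT, -0.28 in M228, -0.23 in M303 and -0.28 in M379. Their SD over fits leaving out a library was 0.15, 0.15, 0.16 and 0.14. M303 thus lay within 1 SD of the bound of -0.1 and cannot decide, while the others lay just over 1 SD or more beyond it. These values argue against that trend as the whole cause in SOX9_WT, M228 and M379.

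Replicate 1 differed from replicates 2 and 3 across all groups, with 2496 genes called, against 0 for replicate 2 and 3 for replicate 3. Each number was tested against the other 2 pooled, so the replicate 1 difference widens the spread in the last 2 tests. Their low counts thus do not show that replicates 2 and 3 are alike. Depth is argued against, as replicate 1 was the deepest library in 2 of the 5 groups and the shallowest in 2 others. With the gene length trend removed 2314 of those genes were still called, which argues against length. A shared library batch or culture day may be the source, as 15 of 15 libraries correlated best, on average, with libraries of their own number. No label names such a batch, and no biological explanation was tested.

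SOX9 reads in SOX9_WT were far below those in the mutants. A swap of single libraries with a mutant is argued against, because the lowest mutant library held 1900 CPM, far above the SOX9_WT mean of 213 CPM, but a relabelling of the whole group stays open. Reads of an introduced transcript missed by the counting cannot be told apart from weaker induction, since the log2 fold change of 0.84 comes from gene counts that do not show where in SOX9 the reads lie.

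With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. For genes, 1 of 10 splits, the real one, called as many as observed in each of the 9 contrasts with a call. The real counts were 5, 39, 19 and 6 against GFP, 92, 62 and 20 against SOX9_WT and 2 and 7 between mutants, and the highest of the other splits was 0 in each. Between M379 and M303 all 10 splits called 0. Other splits that part all pairs called 0 genes too.

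For lists, 5, 5, 5 and 6 of 10 splits gave as many as the real 9, 7, 8 and 6 against GFP (SOX9_WT, M228, M303, M379), with highest other counts of 16, 14, 15 and 12. Against SOX9_WT, 2, 9 and 5 of 10 gave as many as the real 8, 8 and 7 for M228, M303 and M379, with highest others of 9, 11 and 14. Among other splits that part all pairs the highest counts were 5, 6 and 6 for the mutants against GFP and 11 for M303 against SOX9_WT, while the others keep same-numbered libraries together.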

How the results depend on the processing

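Robust dispersion, libraries 2 and 3 of every group, removal of the gene length trend (with or without the block), the estimated correlation with the block, and voom weights were tried after seeing the data. Of the counts of called genes under all alternatives, 54 stayed within 1.5 times the reported count and 122 moved; of the counts of lists 73 stayed and 25 moved. SOX9 kept its direction and its side of the threshold in 98 of 100 values, and named genes kept theirs in 1722, lost the call in 417, gained it in 32 and changed sign in 95. Robust dispersion, seen first, gave 5, 36, 15 and 5 genes against GFP, 93, 63 and 20 against SOX9_WT and 2, 7 and 0 between mutants. A fit with fewer libraries has less power by construction; the cause of the other changes was not tested. Library depth limits GFP replicate 1 most, where 3 reads equal 0.912 CPM. The deposited normalized values were not run for contrasts of M379. Replicate numbers do not pair SOX9_WT with GFP, M228 or M379 by the rule used, although all 15 libraries correlated best with their own number, and the block kept every reported gene call there. It lost the mitosis list call in SOX9_WT against GFP (camera adjusted p = 0.0599) and the enterocyte list call in M228 against SOX9_WT (camera adjusted p = 0.105). It added the mitochondrial and heat shock lists in the first contrast (camera adjusted p = 0.0429 and 0.0163). In M228 against SOX9_WT it added the DNA replication, BMP and TGF-beta, and Paneth cell lists (camera adjusted p = 0.0485, 0.0472 and 0.0485). In M379 against SOX9_WT it added the enterocyte, NF-kB and Paneth cell lists (camera adjusted p = 0.00468, 0.0294 and 0.0377). None of these held with an estimated correlation. By edgeR with the block SOX9 and KRT20 were called in SOX9_WT against GFP (adjusted p = 0.0381 and 0.0337), PROM1 in M228 against SOX9_WT (adjusted p = 0.00143) and PROM1 and KRT20 in M379 against SOX9_WT (adjusted p = 0.0237 and 0.0177). Apart from these and the blocked values printed in the report, the block changed no reported call of a named gene or list. It moved no count of lists by over 1.5 times. Dispersion differs between groups, with a median of 0.0975 in GFP, and a single dispersion per gene gave at most 1 simulated call. In SOX9_WT against GFP, unchanged groups that keep the replicate differences gave 9 to 116 calls when blocked on replicate, and 9 of 20 reached the 78 seen with the block.

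DESeq2 size factors gave 3 genes for M379 minus GFP. DESeq2's Wald test gave 67 genes for SOX9_WT minus GFP, 166 for M228 minus GFP, 89 for M303 minus GFP, 50 for M379 minus GFP, 227 for M228 minus SOX9_WT, 170 for M303 minus SOX9_WT, 71 for M379 minus SOX9_WT, 11 for M303 minus M228 and 23 for M379 minus M228. Testing without a filter on low counts gave 180 genes for SOX9_WT minus GFP, 282 for M228 minus GFP, 212 for M303 minus GFP, 74 for M379 minus GFP, 320 for M228 minus SOX9_WT, 273 for M303 minus SOX9_WT, 137 for M379 minus SOX9_WT, 47 for M303 minus M228, 48 for M379 minus M228 and 5 for M379 minus M303. A stricter filter gave 3 genes for M379 minus GFP and 1 for M303 minus M228. A replicate block gave 79 genes for SOX9_WT minus GFP, 181 for M228 minus GFP, 85 for M303 minus GFP, 17 for M379 minus GFP, 319 for M228 minus SOX9_WT, 259 for M303 minus SOX9_WT, 106 for M379 minus SOX9_WT, 14 for M303 minus M228 and 25 for M379 minus M228. Fitting only the libraries of the compared groups gave 0 genes for SOX9_WT minus GFP, 3 for M228 minus GFP, 2 for M303 minus GFP, 1 for M379 minus GFP, 278 for M228 minus SOX9_WT, 118 for M303 minus SOX9_WT and 165 for M379 minus SOX9_WT. Limma on the deposited normalized values gave 0 genes for SOX9_WT minus GFP, 18 for M228 minus GFP, 4 for M303 minus GFP, 41 for M228 minus SOX9_WT, 10 for M303 minus SOX9_WT and 0 for M303 minus M228. Libraries 2 and 3 of every group gave 1 gene for SOX9_WT minus GFP, 9 for M228 minus GFP, 4 for M303 minus GFP, 3 for M379 minus GFP, 21 for M228 minus SOX9_WT, 7 for M303 minus SOX9_WT, 1 for M379 minus SOX9_WT, 1 for M303 minus M228 and 1 for M379 minus M228. Removing the gene length trend gave 10 genes for SOX9_WT minus GFP, 66 for M228 minus GFP, 150 for M228 minus SOX9_WT, 105 for M303 minus SOX9_WT and 8 for M303 minus M228. Removing it together with the replicate block gave 98 genes for SOX9_WT minus GFP, 332 for M228 minus GFP, 160 for M303 minus GFP, 68 for M379 minus GFP, 462 for M228 minus SOX9_WT, 367 for M303 minus SOX9_WT, 168 for M379 minus SOX9_WT, 33 for M303 minus M228, 36 for M379 minus M228 and 1 for M379 minus M303. Voom with quality weights gave 36 genes for SOX9_WT minus GFP, 42 for M303 minus GFP, 24 for M379 minus GFP, 468 for M228 minus SOX9_WT, 1202 for M303 minus SOX9_WT, 707 for M379 minus SOX9_WT, 14 for M303 minus M228, 34 for M379 minus M228 and 1 for M379 minus M303. Leaving out each library gave 0 to 38 for SOX9_WT minus GFP, 15 to 143 for M228 minus GFP, 4 to 31 for M303 minus GFP, 2 to 12 for M379 minus GFP, 27 to 42 for M228 minus SOX9_WT, 9 to 33 for M303 minus SOX9_WT, 1 to 5 for M379 minus SOX9_WT, 1 to 2 for M303 minus M228 and 0 to 4 for M379 minus M228.

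Fry gave 2 lists for SOX9_WT minus GFP, 2 for M228 minus GFP, 1 for M303 minus GFP, 0 for M379 minus GFP, 2 for M228 minus SOX9_WT, 1 for M303 minus SOX9_WT and 0 for M379 minus SOX9_WT. The estimated correlation gave 0 lists in each of these 7 contrasts, and so did the replicate block with it. Leaving out each library gave 4 to 8 lists for M228 minus GFP, 4 to 9 lists for M303 minus GFP, 1 to 8 lists for M379 minus GFP and 5 to 9 lists for M303 minus SOX9_WT. The SOX9 fold change of SOX9_WT against GFP was called with the replicate block (0.86) and ran from 0.72 to 1.10 when each library was left out. The covariance of fold changes against GFP ran, when each GFP library was left out, from 0.0765 to 0.259 for SOX9_WT and M228, 0.0769 to 0.245 for SOX9_WT and M303, 0.0804 to 0.245 for SOX9_WT and M379, 0.11 to 0.269 for M228 and M303, 0.101 to 0.256 for M228 and M379 and 0.111 to 0.253 for M303 and M379, highest without GFP replicate 3 in each.

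The 5 markers fixed by name, never called in the reported setting, changed sign in these settings (log2 fold changes). With the gene length trend removed, MKI67 was -0.034 in SOX9_WT minus GFP, -0.031 in M228 minus GFP, -0.0067 in M303 minus GFP, 0.0033 in M228 minus SOX9_WT, 0.027 in M303 minus SOX9_WT, 0.040 in M379 minus SOX9_WT and 0.012 in M379 minus M303, and CDX2 was 0.0086 in M303 minus GFP and -0.0027 in M379 minus SOX9_WT. With the replicate block and the length trend removed, MKI67 was -0.028 in SOX9_WT minus GFP, -0.029 in M228 minus GFP, 0.034 in M303 minus SOX9_WT, 0.035 in M379 minus SOX9_WT and 0.00082 in M379 minus M303, and CDX2 was -0.0050 in M379 minus SOX9_WT. Under voom with quality weights, MKI67 was -0.13 in SOX9_WT minus GFP, -0.24 in M228 minus GFP, -0.068 in M303 minus GFP, -0.11 in M379 minus GFP, 0.063 in M303 minus SOX9_WT and 0.025 in M379 minus SOX9_WT, and LGR5 was -0.15 in SOX9_WT minus GFP, and CDX2 was 0.11 in SOX9_WT minus GFP, 0.080 in M303 minus GFP, 0.13 in M379 minus GFP, -0.027 in M303 minus SOX9_WT and 0.052 in M379 minus M303, and KRT20 was -0.036 in M379 minus GFP. Under no filter on low counts, CDX2 was 0.025 in M303 minus GFP. With libraries 2 and 3 of every group, KRT20 was -0.0064 in M303 minus GFP and -0.021 in M379 minus GFP, and MKI67 was 0.11 in M303 minus SOX9_WT, and CDX2 was -0.024 in M303 minus SOX9_WT, -0.016 in M379 minus SOX9_WT and 0.0081 in M379 minus M303. Under DESeq2 size factors, KRT20 was -0.0070 in M379 minus GFP, and MKI67 was 0.0022 in M379 minus M303. Under DESeq2's Wald test, KRT20 was -0.0071 in M379 minus GFP, and MKI67 was 0.0021 in M379 minus M303. Under a stricter filter, KRT20 was -0.0073 in M379 minus GFP. Under a replicate block, KRT20 was -0.0040 in M379 minus GFP. With only the libraries of the compared groups, KRT20 was -0.0066 in M379 minus GFP. MKI67 ran, over fits leaving out a library, from -0.16 to 0.34 in SOX9_WT minus GFP, -0.23 to 0.27 in M228 minus GFP, -0.20 to 0.29 in M303 minus GFP, -0.21 to 0.29 in M379 minus GFP, -0.16 to 0.050 in M228 minus SOX9_WT, -0.14 to 0.065 in M303 minus SOX9_WT, -0.16 to 0.073 in M379 minus SOX9_WT, -0.091 to 0.13 in M303 minus M228, -0.096 to 0.14 in M379 minus M228 and -0.12 to 0.11 in M379 minus M303. LGR5 ran, over fits leaving out a library, from -0.060 to 0.70 in SOX9_WT minus GFP, -0.55 to 0.21 in M228 minus GFP, -0.74 to 0.030 in M303 minus GFP, -0.59 to 0.18 in M379 minus GFP and -0.13 to 0.083 in M379 minus M228. CDX2 ran, over fits leaving out a library, from -0.33 to 0.031 in SOX9_WT minus GFP, -0.27 to 0.13 in M303 minus GFP, -0.31 to 0.046 in M379 minus GFP, -0.16 to 0.25 in M303 minus SOX9_WT, -0.15 to 0.16 in M379 minus SOX9_WT and -0.26 to 0.18 in M379 minus M303. KRT20 ran, over fits leaving out a library, from -0.046 to 0.11 in M303 minus GFP, -0.052 to 0.073 in M379 minus GFP and -0.10 to 0.043 in M379 minus M303. PROM1 ran, over fits leaving out a library, from -0.48 to 0.033 in M379 minus GFP, -0.11 to 0.41 in M303 minus M228 and -0.019 to 0.32 in M379 minus M303.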

Other observations

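The contrasts of the chondrocyte, Notch and enterocyte lists between mutants, the test without COL9A3 and the tests of replicate 1 were chosen after the results were seen.

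Members of the chondrocyte list, tested between mutants after COL9A3 had been seen, had fold changes above 0 in 7 of 7 for M303 against M228 (median 0.30, camera adjusted p = 2.11e-10, adjusted p = 0.056 with an estimated correlation and 0.018 with the replicate block as well). COL9A3 itself is part of that value. Without it the other 6 members, all above 0, had a camera adjusted p of 0.00167 and an adjusted p = 0.67 with an estimated correlation (0.094 with the replicate block as well), which keeps no call. COL9A3 was the called member, and adjusted over the list alone 2 rose. In M379 against M228, 6 of 7 were higher (camera adjusted p = 6.63e-06, adjusted p = 0.20 with an estimated correlation), and without COL9A3 the camera adjusted p was 0.0807. Blocking on replicate, the camera adjusted p without COL9A3 was 0.0340, a call, and 0.199 with an estimated correlation as well. The Notch list was higher in M379 than in M228, with 11 of 12 members above 0 and a median of 0.27 (camera adjusted p = 8.59e-05, adjusted p = 0.028 with an estimated correlation). None of its members was called. The enterocyte list was lower in M379 than in M228 (camera adjusted p = 2.15e-07, adjusted p = 0.30 with an estimated correlation), with 3 members lower adjusted over the list alone.

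In replicate 1, across all groups, interferon, sterol and intestinal transcription factor genes were higher and protein folding genes lower than in replicates 2 and 3. IFIT2, an interferon-induced gene, differed by 1.39, PIGR, the receptor that carries antibodies across the gut epithelium, by 1.12 and ADH1C, an alcohol dehydrogenase gene, by 2.31. FOSL1, an AP-1 transcription factor gene, differed by -1.14. All 4 had an edgeR adjusted p of 9.19e-05 and were chosen after their values were seen. Of the interferon list 11 of 22 members were higher, of the cholesterol synthesis list 12 of 20, of the intestinal transcription factor list 6 of 16, and 11 of 18 unfolded protein response and 11 of 14 heat shock members were lower. With an estimated correlation the camera adjusted p was 0.0489, 0.0374, 0.0489, 0.0374 and 0.0374. The numbers were not assigned as a treatment, so these are differences between libraries.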
